A study of Mus musculus with 11 samples.

How the data were processed

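Gene expression was measured on 11 Illumina Mouse-6 version 1.1 bead arrays, 1 array per sample, in EML cells sorted by surface Sca-1 and in companion cultures. Per the labels, total RNA was isolated with an RNeasy Mini kit (Qiagen), and 10 to 100 ng of it was amplified with a TotalPrep kit (Ambion). Groups were read from the sample titles: Low, Mid and High fractions at day 0 with 2 arrays each, the same fractions at day 6 with 1 array each, Non-sorted cells with 1 array, and cells treated with erythropoietin (Epo) for 7 days with 1 array. At day 0, titles ending in the letter a are called replicate 1 here and titles without it replicate 2. Per the labels, all cells but the Epo culture were untreated.

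The authors deposited probe intensity values on a linear scale, rank-invariant normalized according to the series' design text, and the submitters' processing notes name BeadStudio 3.0. Many values lie below 0, so a background was subtracted at some step. The background setting, the array used as reference and detection p-values are not given in the sources used here, and raw scanner files are not analysed here.

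Probe names hold numbers rather than gene symbols. Of 11857 names with a zero-padded number, 82.6% matched an NCBI Gene ID in the reference table (mouse assembly GRCm38.p6, used for names only), against 46.0% after adding 1 and 41.1% after adding 7 to each number. The 16482 names with unpadded numbers matched in 11.3% and were not named from them. RIKEN clone names, RefSeq accessions and mitochondrial gene names were matched through the same table. Brightness was a check of the naming: 75 of 81 ribosomal protein probes and 18 of 21 proteasome probes had a mean above 50 intensity units, but only 3 of 441 olfactory or vomeronasal receptor probes and 0 of 27 keratin probes. In all, 10799 of 46628 probes were named for 8695 genes, 1819 of them on more than 1 probe, and 550 control probes or probes of unknown form were left out. Genes without a named probe are not analysed here.

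A floor was set at the background mode plus 3 SDs of the values under the mode, as the median over arrays, which gave 20.0 intensity units. The background SD ran from 2.95 on High day 0 replicate 2 to 15.9 on the Mid day 6 array. It was 14.6 and 12.3 on the Mid day 0 arrays. With 1 floor for all, more background can pass there than on the Low and High arrays of day 0. Values under the floor were raised to it and log2 was taken. The 20185 of 46078 probes (43.8%) above the floor on at least 2 of the 11 arrays were tested, with 5638 named probes for 4849 genes among them. Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, with 1 mean for each of the 8 groups and Benjamini-Hochberg adjustment at 0.05. The residual spread came from the 3 day 0 pairs (3 residual degrees of freedom; prior SD 0.110 with 1.16 prior degrees of freedom), and every group of 1 array was assumed to vary like those pairs. For 384 tested probes the floor left no spread in any day 0 pair. That lack of spread entered the fit beside the prior. Their SEs therefore lay below what the prior alone would give, and their p-values may be too small. Comparisons were Low minus High, Low minus Mid and High minus Mid at day 0, Low minus High at day 6, the change of that difference between day 0 and day 6, day 6 minus day 0 over the fractions, and Epo minus Non-sorted. A gene under the floor on every array of 1 group is given as "at least N-fold", the other group's mean log2 value against the floor, or with "at least" before its log2 difference.

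Gene lists were tested with limma's camera at a preset correlation of 0.01, on 1 probe per gene, that with the highest mean; alternatives were an estimated correlation and limma's fry. Of 19 lists, 18 had the required 3 measured members. They held genes of the erythroid, granulocyte and macrophage, megakaryocyte, mast cell, lymphoid, stem and progenitor, and stromal types, of haem synthesis, cell cycle, ribosomal proteins, oxidative phosphorylation, glycolysis, interferon response, antigen presentation, immediate early and heat shock genes, cholesterol synthesis, p53 targets and cytokine receptors, and the Ly6 family. The share of the Low minus High difference left at day 6 was the slope at day 6 over the slope in the other day 0 set, for the 500 probes with the largest difference in the set used for picking, averaged over both choices of that set. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 named the probes and drew the plots.

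Named genes followed a rule: Ly6a, Gata1, Spi1, Epor and Kit whatever their values; the 8 highest and 8 lowest called genes for Low minus High at day 0 and for Epo minus Non-sorted, and the 4 highest and 4 lowest elsewhere, where all arrays of 1 group lay beyond all of the other; and for each list up to 2 called members raised and 2 lowered, or the 2 brightest where no member was called. Genes named outside the rule are said to be so. Groups, comparisons, lists, this rule and the alternatives, except those said to be chosen after seeing the data, were fixed before the data were examined. The alternatives were quantile normalization or cyclic loess on top of the deposited values, a lower and a higher floor, a generalised log without a floor, no filter or a stricter filter on dim probes, eBayes with trend and robust settings, a fit on the day 0 arrays, a replicate block, leaving out each day 0 array, the other list tests, and other numbers of picked probes.

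Each step was tested on simulated data. With 200 changed probes among 20185, the Low minus High test at day 0 called 30.0% of them at a log2 change of 1 and 90.0% at 2, with 4 and 6 unchanged probes called; the Epo minus Non-sorted test called 0% and 72.5%, with 0 and 4 unchanged probes called. A list of 12 genes shifted by 1 on the log2 scale had an adjusted p of 5.96e-22 in the Low minus High test at day 0, and 0 of 17 unshifted lists were called. The simulated noise was independent between probes, had the same SD in all groups and was not held at the floor. These runs therefore do not show how the list test behaves for correlated genes. In the data the day 0 pairs differed in spread, and far more than 200 probes were called in both comparisons. The simulated percentages and false calls need not carry over to them. A share left of 0.3 put into the simulation came back as 0.300 on average over 20 draws, with a range of 0.249 to 0.346.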

Results

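The arrays measured RNA of EML cells, a mouse multipotent blood progenitor line that can form erythroid, myeloid and lymphoid cells in culture. A clonal population had been sorted by surface Sca-1, the product of Ly6a and an antigen of blood stem and progenitor cells, into fractions of 15% each, called Low, Mid and High. Each fraction had 2 arrays at day 0 and 1 at day 6. Non-sorted cells and cells given erythropoietin (Epo), the hormone that drives red cell formation, had 1 array each. These 11 arrays form 8 groups. Their number limits the precision, and the day 6, Non-sorted and Epo groups have no replicate. Whether the 2 day 0 arrays of a fraction came from separate sorts or cultures is not stated, so p-values may measure technical spread only. The study's title concerns transcriptome-wide noise and differentiation potential. The comparisons ask which transcripts differed between cells of a clone sorted by Sca-1, how far this held at day 6, and how it compares with the Epo culture.

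Between 33.2% and 38.3% of the 46078 probes lay above the floor of 20.0 intensity units, and array medians ran from 0.574 to 6.86. The bright range differed between the day 0 fractions: the 99th percentile was 6529 and 6851 on the High arrays, 9770.1 and 9237 on the Low arrays, and 10957 and 11283 on the Mid arrays. In the brightest of 6 equal groups of tested probes the median Low minus High difference at day 0 was 0.40 on the log2 scale as deposited and 0.03 after quantile normalization. A dim range differed from Mid as well. In group 2 of 6, counted from the dimmest, the deposited medians were −0.37 for Low minus Mid and −0.21 for High minus Mid. After quantile normalization they were −0.02 and 0, but after cyclic loess −0.20 and −0.10. The cause of this dim shift was not tested. Ly6a, Gata1, Spi1, Epor and Kit had no named probe and are not analysed here.

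At day 0, Low cells carried far more RNA of the red cell genes Car1, Hba-a1 and Hbb-b2 than High cells. Car1, a carbonic anhydrase abundant in red cells, read 13637 ± 463 in Low and 64.9 ± 44.5 in High (mean ± SD, n = 2 each), a log2 difference of 7.91 ± 0.56 (SE; adjusted p = 0.0104). Hba-a1, an adult alpha globin, read 7319 ± 179 against 34.2 ± 6.38, a difference of 7.76 ± 0.34 (adjusted p = 0.00570). Hbb-b2, a beta globin, was higher by 3.42 ± 0.28 (adjusted p = 0.0115). Globin genes have near-identical copies, so these probes may also bind RNA of a copy. Gml2 was higher by 5.04 ± 0.18 (adjusted p = 0.00517). Dennd2d, Glipr2, Prnp, the prion protein gene, and Nmnat3, an enzyme of NAD synthesis, were higher by 2.51, 2.497, 2.48 and 2.44, with adjusted p between 0.00854 and 0.0279.

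Bcl3, Fbxw5 and Bcl2l1 were among the genes lower in Low than in High. Bcl3, a nuclear partner of NF-kappa-B, read 21.4 ± 1.26 in Low and 274 ± 111 in High, a log2 difference of −3.62 ± 0.33 (adjusted p = 0.0137). Fbxw5 differed by −3.17 ± 0.25 (adjusted p = 0.0114) and Bcl2l1, which encodes the anti-apoptotic Bcl-xL, by −3.14 ± 0.35 (adjusted p = 0.0173). Nrp1, Rasgrp4, P2rx3, Rab3il1 and Fmnl1 differed by −3.28, −3.07, −3.07, −2.78 and −2.69, with adjusted p between 0.0135 and 0.0443. Nrp1, Rab3il1 and Fmnl1 were above the floor on 1 of 2 Low arrays, and Nrp1 missed the threshold after quantile normalization at a difference of −3.01 (adjusted p = 0.0612).

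Of the 12 measured erythroid genes, 8 were higher in Low and 0 lower, also when adjusted over the list alone. Their median log2 difference was 0.87 and their mean 2.08. Of the 46 genes in that list, 13 had a named probe. The list rose (camera adjusted p = 0.00122; adjusted p = 0.431 with an estimated correlation). Ank1, an ankyrin of the red cell membrane, and Hba-x, an embryonic globin, were chosen after their values were seen. Both were below the floor on both High arrays, with log2 differences of at least 1.33 and at least 0.71 (adjusted p = 0.00854 and 0.0313). Of 3 haem synthesis genes 2 were called higher, Tmem14c among them (0.80), and all 3 when adjusted over the list alone. The list missed the threshold (camera adjusted p = 0.0535). The granulocyte and macrophage list fell, with 4 of 11 members lower and 2 higher, the same counts when adjusted over the list alone (camera adjusted p = 0.00993; adjusted p = 0.431 with an estimated correlation). Lyz2, lysozyme, was at least 4.82-fold lower (adjusted p = 0.0133) and Cebpa, a transcription factor of myeloid commitment, at least 4.78-fold lower (adjusted p = 0.00854), while Fcgr2b and Anxa1 differed by −2.01 ± 0.12 and −2.04 ± 0.12. Mpo, myeloperoxidase, was higher by 0.56 ± 0.11 (adjusted p = 0.0436). It was called lower after quantile normalization, at −1.04 (limma adjusted p = 0.0184), and stood at −0.13 after cyclic loess. In the lymphoid list 2 of 7 genes were lower and 0 higher, again the same when adjusted over the list alone (camera adjusted p = 0.00993; adjusted p = 0.431 with an estimated correlation). These were Gata3, a transcription factor of the T lineage, with −1.72 ± 0.10 (adjusted p = 0.00854) and Satb1, a chromatin organiser, with −1.42 ± 0.12 (adjusted p = 0.0127).

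Bright housekeeping lists were also higher in Low than in High, where the scale of the bright range differed. Of 71 ribosomal protein genes 55 were higher and 0 lower, 61 and 1 when adjusted over the list alone (camera adjusted p = 6.09e-14; adjusted p = 0.431 with an estimated correlation). The list test also passed after quantile normalization (adjusted p = 0.00522). Rps14 and Rps4x, higher by 1.40 ± 0.21 and 1.39 ± 0.21, missed the threshold after quantile normalization, Rps14 at 0.39 (adjusted p = 0.345) and Rps4x at 1.0005 (adjusted p = 0.0736). Oxidative phosphorylation genes were called higher in 18 of 54 cases and lower in 0, or 29 and 1 when adjusted over the list alone (camera adjusted p = 4.81e-05; adjusted p = 0.431 with an estimated correlation). The direction of that list test turned after quantile normalization (adjusted p = 0.894), and Cox5b went from 1.03 to −0.02. Glycolysis genes were higher in 8 of 13 cases and lower in 0, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.431 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.943). Ldha was higher by 1.28 ± 0.13 and Pfkm by 1.35 ± 0.06, although another Pfkm probe was called lower.

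The interferon response list fell, with 3 of 8 genes lower and 0 higher, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.0346; adjusted p = 0.431 with an estimated correlation). Igtp, an interferon-induced GTPase, and Irf1, a transcription factor of this response, differed by −1.50 ± 0.21 and −1.24 ± 0.12. That list missed the threshold after quantile normalization (adjusted p = 0.173), and without Low replicate 1, Low replicate 2 or High replicate 2 (adjusted p = 0.103, 0.0692 and 0.111). The antigen presentation list fell as well (camera adjusted p = 0.0325; adjusted p = 0.431 with an estimated correlation). It had 1 of 9 genes lower and 1 higher, or 2 and 1 when adjusted over the list alone, and missed the threshold without High replicate 1 (adjusted p = 0.0749). H2-D1, a class I antigen, differed by −1.99 ± 0.23, and Psmb10, an immunoproteasome subunit, by 0.73 ± 0.14.

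The remaining lists missed the camera threshold in this comparison. With fry, haem synthesis, cell cycle and cholesterol synthesis passed as higher in Low (fry adjusted p = 0.0148, 0.0362 and 0.0458). Antigen presentation missed the threshold with fry (adjusted p = 0.0612). Stem and progenitor genes went both ways, with 2 of 7 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.710). The median of that list was 0, its mean above 0 and its test direction down, which turned after either scaling. Lmo2, a partner of the erythroid transcription complex, was higher by 1.66 ± 0.18, Slamf1 was at least 1.71-fold higher, and Runx1 differed by −1.02 ± 0.08. Of 19 cell cycle genes 3 were higher, including Cenpa and Cdc6 (0.97 and 0.60), and 8 when adjusted over the list alone (camera adjusted p = 0.189). The direction of that test turned after either scaling. Immediate early and heat shock genes were higher in 4 and lower in 3 of 9 cases, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.558). Hspa8, a chaperone, was higher by 1.20, and Junb and Klf6 differed by −1.68 and −0.89. Of 5 megakaryocyte genes Nfe2 was higher (0.83) and Fli1 lower (−1.23), or 1 and 2 when adjusted over the list alone (camera adjusted p = 0.405). Il1rl1, higher by 0.91, was the called member of the mast cell list (1 of 5; camera adjusted p = 0.781) and of the cytokine receptor list (1 of 7; camera adjusted p = 0.153). Adjusted over the list alone, 1 was higher and 1 lower in the mast cell list, whose direction turned after either scaling, and 1 higher and 3 lower in the receptor list. Cholesterol synthesis had 1 of 15 genes higher, Nsdhl (0.66), and 1 lower, or 1 and 0 when adjusted over the list alone (camera adjusted p = 0.596); that list's direction turned after either scaling. Of 7 p53 targets Cdkn1a, a cell cycle inhibitor, was lower (−0.77), or 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.516, with the median above 0, the mean below 0 and the test direction down). Of 3 stromal genes 0 were called, also when adjusted over the list alone (camera adjusted p = 0.898). The stromal median was 0, the mean above 0 and the test direction down, which turned after cyclic loess. The Ly6 family had 2 measured members and was not tested. Ly6e was higher by 0.89 and stood at −0.49 after quantile normalization.

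In all, limma called 3553 of 20185 probes between Low and High at day 0, 2376 higher in Low and 1177 lower (66.9% higher). After quantile normalization 2526 were called (51.6% higher), of which 2185 were among the 3553, and after cyclic loess 2596 (48.1% higher), of which 2236 were. The count rests on both arrays of a pair: it was 17 and 15 without Low replicate 1 and 2, 12 and 13 without High replicate 1 and 2, and 2078 and 2084 without Mid replicate 1 and 2. Of the 47 genes examined here, 0 kept their call when any single Low or High array was left out, and 29 kept it when either Mid array was, with the same direction throughout. With no filter the count was 173, and 44 of the 47 genes lost the call. With the replicate block the count was 1188, and 17 of the 47 lost it. After quantile normalization the calls of Tmem14c, Nfe2, Il1rl1, Cenpa, Cdc6, Psmb10, Hspa8 and Nsdhl were also lost (adjusted p between 0.0541 and 1), with the difference of Il1rl1 at 0.80 still near its size, and after cyclic loess also those of Cox5b and Ly6e (adjusted p = 0.0672 and 0.24).

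**Figure D1:**
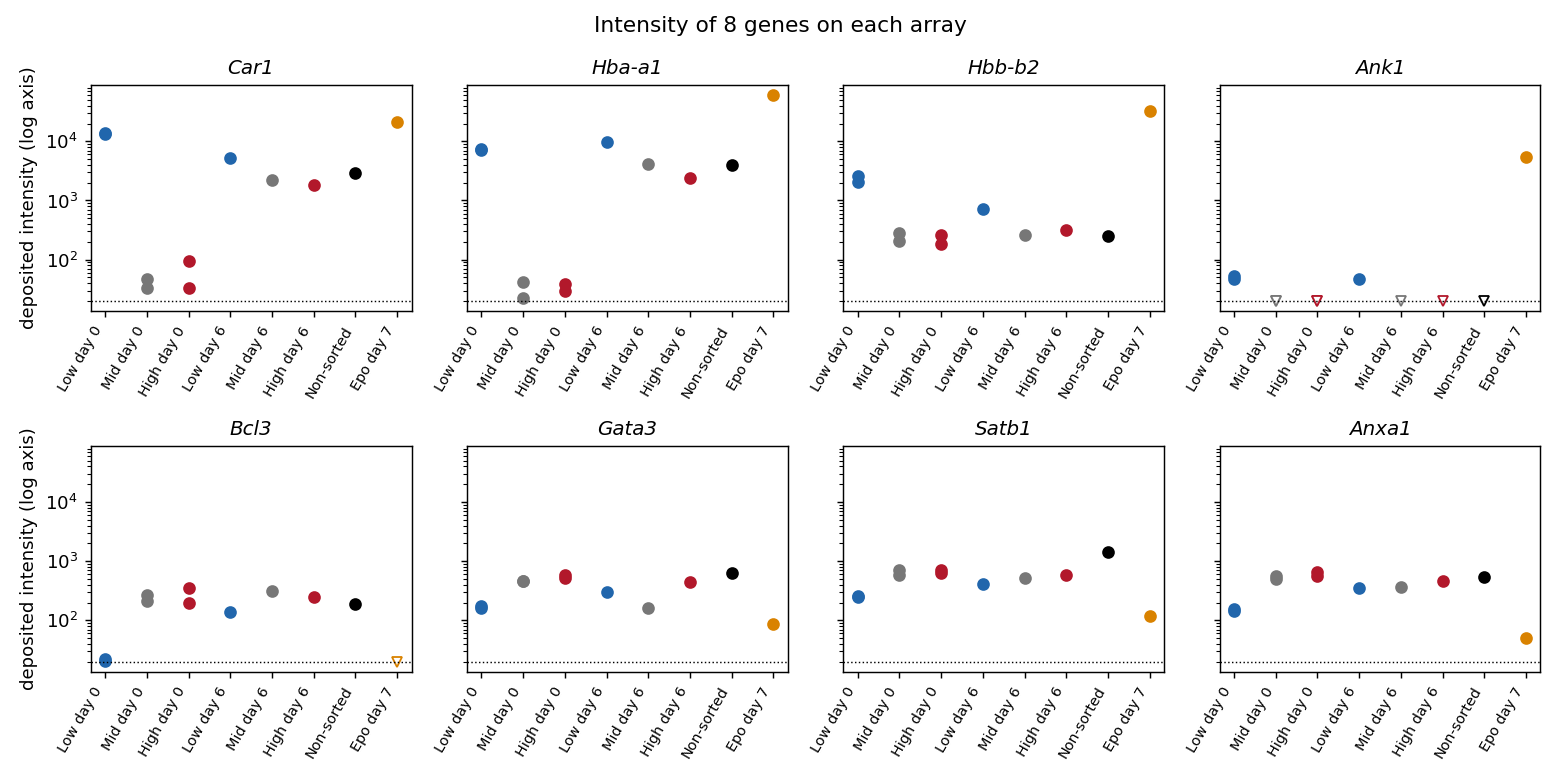
Deposited intensity on a log axis of Car1, Hba-a1, Hbb-b2, Ank1, Bcl3, Gata3, Satb1 and Anxa1 in the 8 groups; each point is 1 array, and open triangles on the dotted line at 20.0 stand for values at or below the floor. Car1 and Hba-a1 averaged 13637 and 7319 in Low at day 0 against 64.9 and 34.2 in High, and Ank1 reached 5529 in the Epo culture.

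**Figure D2:**
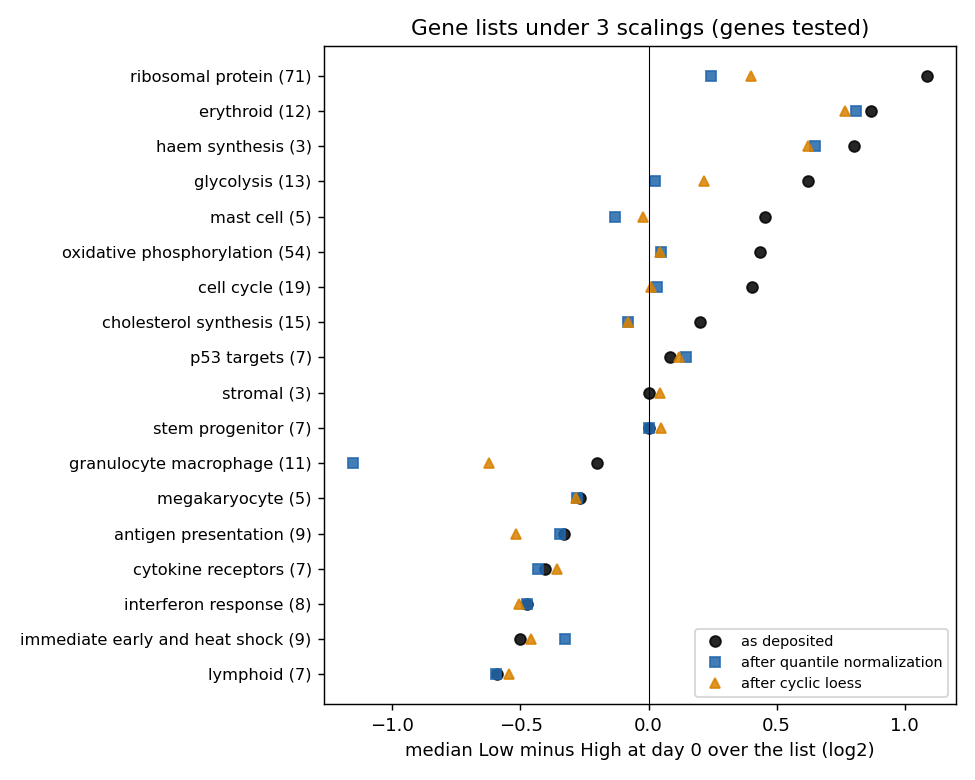
Median log2 difference, Low minus High at day 0, over the measured genes of each of 18 lists, as deposited, after quantile normalization and after cyclic loess; the stromal list has no point after quantile normalization. The ribosomal protein median moves from 1.09 as deposited to 0.24 after quantile normalization, and the cholesterol synthesis and mast cell medians turn from above to below 0 after either scaling.

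Mid cells at day 0 had little of the erythroid RNA of Low cells, at levels near those of High cells. Car1 and Hba-a1 read 39.9 ± 10.3 and 32.3 ± 13.6 in Mid (n = 2), so that Low exceeded Mid by 8.44 ± 0.56 and 7.89 ± 0.34 on the log2 scale (adjusted p = 0.00661 and 0.00477). Gml2, Hbb-b2 and Lmo2 were higher in Low by 4.13, 3.26 and 0.99, and Pfkm by 1.09. Fbxw5, Bcl3, Rasgrp4 and P2rx3 differed by −3.49, −3.49, −3.22 and −3.09, Gata3 and Satb1 by −1.47 and −1.34. Anxa1, Itga2b, Irf1, B2m and Cdkn1a differed by −1.83, −0.96, −1.44, −1.24 and −1.05. Cebpa was at least 4.73-fold lower. The erythroid list was higher in Low, with 6 of 12 genes higher and 0 lower, or 7 and 0 when adjusted over the list alone (camera adjusted p = 4.08e-05; adjusted p = 0.591 with an estimated correlation). The granulocyte and macrophage list was lower, with 6 of 11 genes lower and 0 higher, the same when adjusted over the list alone (camera adjusted p = 0.000716; adjusted p = 0.591 with an estimated correlation). Antigen presentation genes were lower in 3 of 9 cases and higher in 0, or 4 and 0 when adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.604 with an estimated correlation). That list missed the threshold without Low replicate 1, Mid replicate 2, High replicate 1 or High replicate 2 (adjusted p = 0.0579, 0.231, 0.0711 and 0.0711). Ribosomal protein genes were lower in Low in 37 of 71 cases and higher in 1, or 43 and 1 when adjusted over the list alone (camera adjusted p = 1.01e-08; adjusted p = 0.604 with an estimated correlation). After quantile normalization that list, Rpl38 (−1.62) and Rps20 (−1.62) missed the threshold (adjusted p = 0.451, 0.0981 and 0.222) and Gapdh turned from −1.099 to 0.16.

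Between Low and Mid 3962 probes were called, 1574 higher in Low and 2388 lower (39.7% higher), and after quantile normalization 3409 (49.6% higher). The count was 23 without Low replicate 1 and 23 without Low replicate 2, and 2261 and 2235 without High replicate 1 and 2. All 21 genes examined lost the call without either Low array. Of the 3553 probes called between Low and High, Mid lay between them for 1912 (53.8%), beyond High for 895 and beyond Low for 746, and its median position was 0.676 with Low at 0 and High at 1.

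Among the genes called between High and Mid cells were mitochondrial, histone and ribosomal protein genes, but no erythroid gene. Hba-a1 differed by 0.13 ± 0.34 (adjusted p = 0.845; −0.06 without High replicate 1 and −0.31 without Mid replicate 2) and Gata3 by 0.26 ± 0.10 (adjusted p = 0.187). Of the 12 erythroid genes limma called 0, also when adjusted over the list alone (camera adjusted p = 0.765; median 0, mean below 0, test direction up). Most calls were lower in High. The mitochondrial genes CYTB and ND1 differed by −2.96 ± 0.17 and −2.81 ± 0.17, the histone genes H2ac10 and H2ac20 by −2.81 ± 0.20 and −2.79 ± 0.22. Rpl23 and Hspa8 differed by −2.75 and −2.68. Zfp444 was at least 5.51-fold and Kdm5c at least 3.14-fold higher in High, and ND4L, Rad51c and Egr2 were higher by 1.70, 1.484 and 0.63. Ribosomal protein genes were lower in 55 of 71 cases and higher in 0, or 58 and 1 when adjusted over the list alone (camera adjusted p = 7.65e-22; adjusted p = 0.807 with an estimated correlation). That call was kept after quantile normalization (adjusted p = 3.24e-05). Oxidative phosphorylation genes were lower in 21 of 54 cases and glycolysis genes in 8 of 13, or 34 and 10 when adjusted over the list alone (camera adjusted p = 4.01e-08 and 0.00110; adjusted p = 0.807 with an estimated correlation for both). The directions of both list tests turned after quantile normalization (adjusted p = 0.974 and 0.960).

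In this comparison 2559 probes were called, 446 higher in High and 2113 lower (17.4% higher). After quantile normalization 1060 were called (34.7% higher) and after cyclic loess 1577 (29.0% higher). Quantile normalization ended the calls of CYTB, ND1, H2ac10, H2ac20, ND4L, Kdm5c, Rps20, Cox6c, Hspa8 and Egr2 (adjusted p between 0.0526 and 0.577). The differences of ND4L (1.77), Kdm5c (1.57) and Egr2 (0.59) stayed near their size, while those of CYTB (−1.40), H2ac20 (−0.91), Rps20 (−0.63) and Cox6c (−0.27) shrank. The same scaling moved Mpo from −2.26 to 0.00, Gapdh from −2.33 to 0.14 and Tmem14c from −0.80 to 0.26. Without High replicate 1 or 2 limma called 0 probes (with all arrays 5994 at unadjusted p under 0.05), and without Low replicate 1 or 2 it called 793.

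At day 6 the Low and High fractions were closer together, with Low above High in Hba-a1 and Car1 and below it in Gata3 and Satb1, as at day 0. Hba-a1 read 9695 in Low, 4104 in Mid and 2364 in High, and Car1 5165, 2235 and 1806. The log2 difference between Low and High was 2.04 ± 0.48 for Hba-a1 (adjusted p = 0.283), −0.57 ± 0.14 for Gata3 (adjusted p = 0.297), −0.49 for Satb1, −0.39 for Runx1, 0.25 for Lmo2, 0.25 for Nfe2 and 0.35 for Rps27a. Mpo stood at 0.02 as deposited, −0.30 after quantile normalization and −0.08 after cyclic loess. With 1 array a side limma called 0 probes (2021 at unadjusted p under 0.05, lowest adjusted p 0.0961), but 1309 and 1299 without Mid replicate 1 and 2 of day 0. As lists, erythroid genes were higher in Low (3 of 12 higher and 0 lower when adjusted over the list alone; camera adjusted p = 4.10e-05; adjusted p = 0.414 with an estimated correlation). Granulocyte and macrophage genes were lower (0 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000744; adjusted p = 0.414 with an estimated correlation). Ribosomal protein and oxidative phosphorylation genes were higher (camera adjusted p = 1.36e-05 and 0.000152; adjusted p = 0.658 and 0.540 with an estimated correlation). The ribosomal call was lost after quantile normalization (adjusted p = 0.116). Interferon response and cholesterol synthesis genes were lower (camera adjusted p = 0.0201 and 0.00676; adjusted p = 0.540 and 0.414 with an estimated correlation). The interferon call was lost without Mid replicate 1 or 2 (adjusted p = 0.0520 and 0.0514). Adjusted over the list alone, 0 genes were called in any of these 4 lists. With fry 0 of 18 lists passed.

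The share of the day 0 difference left at day 6 was 0.285, from 0.258 and 0.312 with either day 0 set used for picking probes. On an axis with Low at 0 and High at 1 at day 0, the day 6 arrays lay at 0.488 and 0.537 for Low, 0.738 and 0.809 for Mid, and 0.746 and 0.849 for High, the 2 values being those of the 2 picking sets. The Non-sorted array lay at 0.448 and 0.535. A direct test of the change, the day 0 difference minus the day 6 difference, called 16 probes. Hba-a1 (5.72 ± 0.59, adjusted p = 0.117), Gata3 (−1.15 ± 0.17, adjusted p = 0.135), Lmo2 (1.42, adjusted p = 0.169) and Ldha (1.27, adjusted p = 0.144) did not pass it. The difference was larger at day 0 for the ribosomal protein and glycolysis lists (camera adjusted p = 2.55e-10 and 0.0109; adjusted p = 0.653 with an estimated correlation for both; 0 and 8 members called higher when adjusted over the list alone). Both calls were lost after quantile normalization (adjusted p = 0.136 and 0.643). The glycolysis call was also lost without High replicate 2 (adjusted p = 0.0683).

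**Figure D3:**
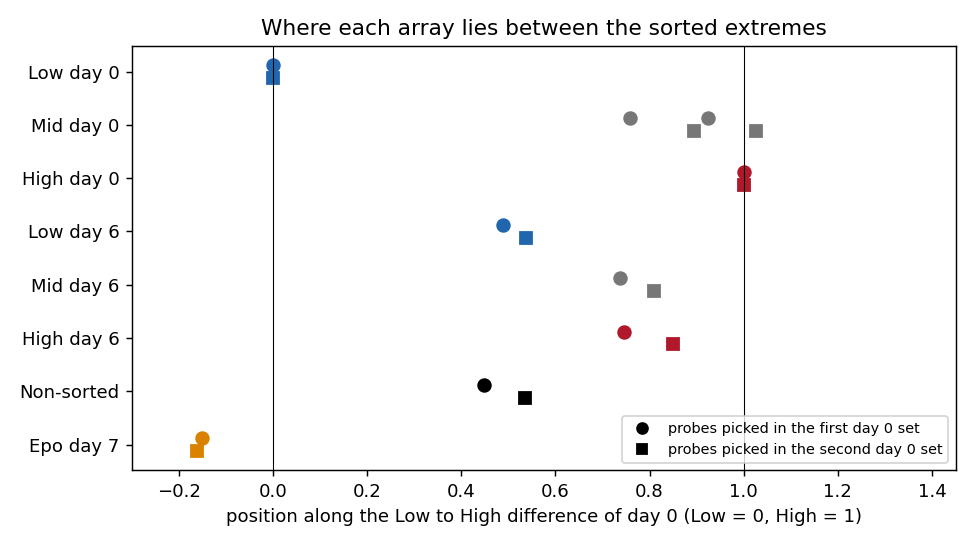
Position of each array between the Low (0) and High (1) fractions of day 0 over the 500 probes with the largest difference; circles and squares stand for probes picked in the first and in the second day 0 set. Day 6 Low lies at 0.488 and 0.537, Non-sorted at 0.448 and 0.535, and the Epo culture beyond Low at −0.150 and −0.161.

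Over the 3 fractions together, day 6 cells had more RNA of Hba-a1 and Car1 and less of the immediate early genes Egr2 and Klf6 than day 0 cells. Hba-a1 was higher at day 6 by 4.53 ± 0.24 (adjusted p = 0.0115) and Car1 by 3.14 ± 0.40 (adjusted p = 0.0218), from Mid and High arrays that had little of either at day 0. In Low, Car1 went from 13637 to 5165. Hbb-b2, at −0.35 ± 0.20, was not called (adjusted p = 0.283). The erythroid list had 2 of 12 genes higher and 0 lower, or 2 and 1 when adjusted over the list alone, and missed the threshold (camera adjusted p = 0.516). Egr2, a transcription factor, was at least 5.73-fold lower (adjusted p = 0.00502) and Klf6 differed by −1.67 ± 0.08 (adjusted p = 0.0115). Their list, immediate early and heat shock genes, had 2 of 9 lower and 1 higher, or 2 and 2 when adjusted over the list alone, and missed the threshold (camera adjusted p = 0.370). Egr2 was above the floor on 0 of 3 day 6 arrays and 6 of 6 day 0 arrays. Cxcl2, a chemokine, was at least 3.99-fold lower, and Osgin1 and the histone gene H2bc3 differed by −1.87 and −1.79. Lrrc29, Mypop, Med13l and Amn1 were higher by 1.26, 1.20, 1.16 and 1.15. Mpo, Lyz2 and Acat2 were higher by 1.097, 0.85 and 0.54, and Cebpb differed by −0.41. Of 71 ribosomal protein genes 37 were higher, among them Rpl37 and Rpl23 (1.14 and 1.09), and 3 lower, among them Rps15a and Rplp0 (−1.55 and −0.56), or 49 and 6 when adjusted over the list alone (camera adjusted p = 1.01e-10; adjusted p = 0.706 with an estimated correlation). After quantile normalization that list missed the threshold (adjusted p = 0.0655), as did Rpl37, Rpl23, Hspa8 (1.09), Amn1, Lyz2 and Cebpb, and Gapdh turned from 0.88 to −0.01. The differences of Amn1 (1.03), Lyz2 (0.78) and Cebpb (−0.36) stayed near their size with that scaling, and those of Rpl37 (0.31) and Rpl23 (0.34) shrank. In all 3076 probes were called, 1594 higher and 1482 lower, and 222 of them had no day 0 spread of their own. With such probes left out, a setting chosen after the results were seen, 1267 were higher and 1368 lower. The balance also depends on the filter: 2342 were higher and 560 lower with no filter, and 974 and 1503 with the stricter filter. Without Low replicate 1 or 2 of day 0 limma called 0 probes (with all arrays 7095 at unadjusted p under 0.05). The count was 807 and 761 without High replicate 1 and 2, and 4833 without Mid replicate 1.

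The Epo culture carried the RNA of maturing red cells. Ank1 read 5529 and was at least 276-fold higher than in Non-sorted cells (adjusted p = 0.000418), Hba-x at least 124-fold (adjusted p = 0.00126) and Dmtn at least 121-fold. Dmtn encodes a cytoskeletal protein of the red cell membrane, and its probe had no day 0 spread. Hbb-b2 rose from 253 to 32035, a log2 difference of 6.99 ± 0.39 (adjusted p = 0.00313), and Hba-a1 differed by 3.91 ± 0.48 (adjusted p = 0.0121). Car1 differed by 2.89 ± 0.80 and missed the threshold (adjusted p = 0.0729). The porphyrin transporter gene Abcb6 was higher by 2.54 ± 0.32 (adjusted p = 0.0126), and Tmem14c by 1.95. Tmcc2 and Ube2l6 were at least 33.4-fold and 33.2-fold higher, and Arrb1 and St3gal6 higher by 4.73 and 4.63. Of 12 erythroid genes 9 were higher and 0 lower, or 10 and 0 when adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.384 with an estimated correlation). All 3 haem synthesis genes were higher, also when adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.513 with an estimated correlation). That call was lost without Mid replicate 1 or 2 (adjusted p = 0.0698 and 0.0699).

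Mcpt4, Slc18a2, Gata3 and Satb1 were lower in the Epo culture. Mcpt4, a mast cell protease, was at least 10.9-fold lower and Slc18a2, a monoamine transporter of mast cell granules, differed by −1.90 ± 0.24. The mast cell list fell, with 2 of 5 lower and 0 higher, or 4 and 0 when adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.513 with an estimated correlation). Satb1 and Gata3 differed by −3.57 ± 0.17 and −2.86 ± 0.14 (adjusted p = 0.00279 and 0.00279). They were the called genes of 7 in the lymphoid list, also when adjusted over the list alone (camera adjusted p = 0.153; median 0, mean below 0, test direction down). Of 11 granulocyte and macrophage genes 6 were lower, Anxa1 (−3.43) and Fcgr2b (−2.39) among them, and Cebpb was higher (2.45), or 6 and 3 when adjusted over the list alone. That list missed the threshold (camera adjusted p = 0.153). Fli1, of the megakaryocyte list, and Runx1 differed by −2.25 and −1.44, and Slamf1 was higher by 1.99. Cd69, an activation antigen, and Ccnd1, a cyclin of the early cell cycle, differed by −4.86 ± 0.19 and −4.14 ± 0.19. Egr2 and Nlrc4 were at least 28.0-fold and 16.0-fold lower. S100a4, Kif3c, Fbxw5 and Gng2 differed by −3.94, −3.88, −3.83 and −3.80.

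Insig1 and Ccng1 were among the genes higher in the Epo culture. Some lists that missed the threshold with camera passed with fry. Among them were cholesterol synthesis and p53 targets as higher, and the granulocyte and macrophage and lymphoid lists as lower. Cholesterol synthesis had 7 of 15 genes higher and 0 lower, the same when adjusted over the list alone, with Mvk and Insig1 at 3.20 ± 0.74 and 2.72 ± 0.12. That list missed the threshold (camera adjusted p = 0.112). Of 7 p53 targets 4 were higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.112). Ccng1, Zmat3 and the cell cycle inhibitor Cdkn1a were higher by 3.81 ± 0.29, 3.01 ± 0.43 and 2.06, and Pmaip1, a pro-apoptotic gene, differed by −2.37 ± 0.30. The cell cycle list had 2 of 19 genes higher, Ube2c (2.28) and Mki67 (0.70), or 1 when adjusted over the list alone (camera adjusted p = 0.715). Its median lay below 0, its mean above 0 and its test direction was up, which turned after quantile normalization. Oxidative phosphorylation genes were higher in 21 of 54 cases and lower in 1, or 28 and 1 when adjusted over the list alone, with Ndufb4 and Ndufa6 at 2.27 and 1.42 (camera adjusted p = 1.25e-07; adjusted p = 0.513 with an estimated correlation). Ribosomal protein genes were higher in 19 of 71 cases and lower in 0, or 28 and 0 when adjusted over the list alone (camera adjusted p = 1.85e-09; adjusted p = 0.566 with an estimated correlation). That list missed the threshold after quantile normalization (adjusted p = 0.0719), as did Rps27l (1.31), Rps7 (1.18), Mki67, Pkm (−1.38), Irf7 (1.63), B2m (1.16) and Mvk (adjusted p between 0.0509 and 0.212). The differences of Irf7 (1.59) and Mvk (3.08) hardly changed with that scaling and that of Pkm grew (−1.62), while those of Rps27l (0.74), Rps7 (0.52), Mki67 (0.47) and B2m (0.55) shrank. Interferon response genes went both ways, with 2 of 8 higher and 3 lower, or 2 and 4 when adjusted over the list alone (camera adjusted p = 0.182). Igtp was higher by 1.453, and Irf1 and Ifi47 differed by −2.35 and −2.11. Pfkm was higher by 1.57, Hspe1 by 1.62, Klf6 by 1.24 and Psca by 2.44. Tnfrsf1a, Tgfbr1 and Ly6e differed by −2.20, −1.70 and −0.76. Klf6, Tnfrsf1a and Ly6e lost the call with the 6 day 0 arrays in place of the Non-sorted array, an alternative chosen after seeing the data.

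With 1 array a side, 4722 probes were called between the Epo culture and Non-sorted cells, 2423 higher and 2299 lower, and 117 of them had no day 0 spread of their own. The count was 2571 and 2568 without Low replicate 1 and 2 of day 0, which enter here through the spread. With the 6 day 0 arrays in place of the Non-sorted array it was 6074.

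Low cells differed from High cells partly in the way the Epo culture differed from Non-sorted cells. Across the tested probes, which are not independent replicates, Pearson's r between the 2 differences was 0.397 (Spearman's rho 0.309), and 0.368 and 0.380 with the first and the second day 0 set alone. The 2 differences share no array. At day 6 the Low minus High difference gave r = 0.249, and Mid minus High at day 0 gave r = 0.106. Among 1649 probes called in both comparisons 84.1% had the same sign: 774 were higher in both and 612 lower in both, with 189 higher in Low and lower in the Epo culture and 74 the other way. The calls of both comparisons rest on the same day 0 spread. Ank1, Hba-a1 and Hbb-b2 were higher in both, and Bcl3, Fbxw5 and Gata3 lower in both.

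**Figure D4:**
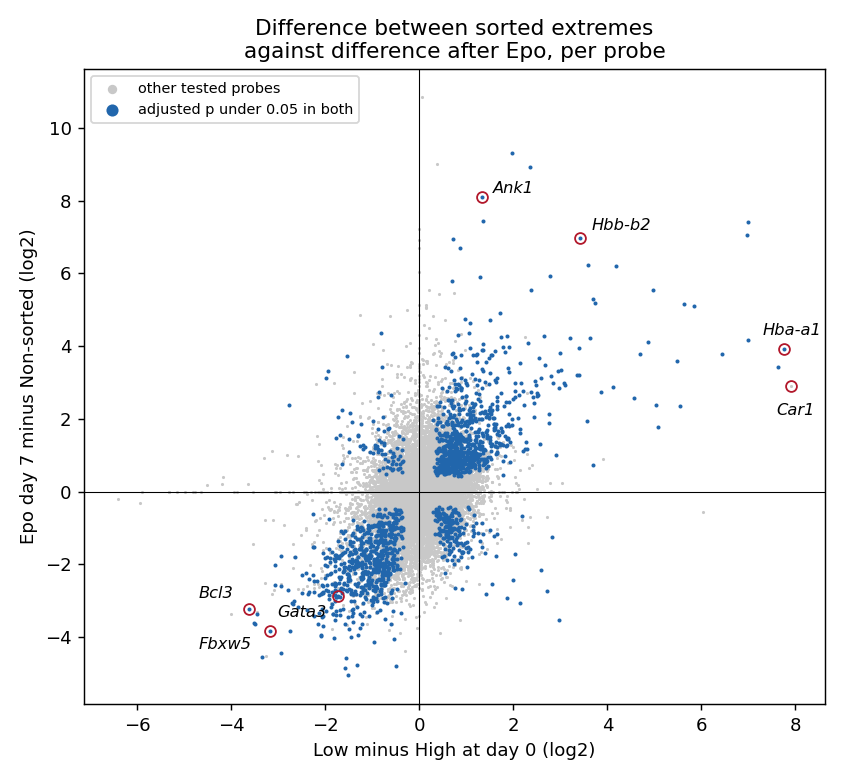
Each point is a tested probe, with the log2 difference Low minus High at day 0 on the x axis and Epo minus Non-sorted on the y axis; blue points were called in both comparisons and circles mark 7 named genes. Of the blue points, 774 lie above 0 and 612 below 0 on both axes.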

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

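The tests of 2 explanations in this part were written before their results were seen; the look at the Epo culture, and the setting without both Mid arrays, were chosen after.

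The difference between Low and High cells changed between day 0 and day 6: the test of that change itself called 16 probes, 15 with a larger positive difference at day 0 and 1 with a larger negative one. For 12 of the 15, all Mid and High arrays of day 0 were below the floor, and 13 of the 15 were also called higher in the Epo culture than in Non-sorted cells. Pairs held at the floor add no spread to the fit, so such probes pass this test more easily. The Epo call rests on the same day 0 spread, so neither count is separate support. The probe scl33630.8_639-S, which has no gene name here, read 3969 in Low at day 0, 1027 at day 6 in Low and 511 in High, with a log2 change of at least 6.62 (adjusted p = 0.00409), and scl23903.13_130-S changed by at least 5.31 (adjusted p = 0.00503), since High at day 0 was below the floor for both. The negative probe, scl51891.20_359-S, read 211 in Low, 1298 in Mid and 1368 in High at day 0 and between 951 and 1029 in all 3 fractions at day 6, a change of −2.73 ± 0.13 (SE; adjusted p = 0.0353), and was lower in the Epo culture. Without Low or High replicate 1 or 2 limma called 0 probes (with all arrays 3554 at unadjusted p under 0.05), without Mid replicate 1 or 2 it called 1434 and 1426, and without both Mid arrays 1021. Most of these were negative, unlike the 16: 912 of 1434, 906 of 1426 and 673 of 1021, and with no filter 394 of 682.

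The smaller difference at day 6 was weighed against 2 technical explanations. Had the scale of the bright range at day 0 made it, quantile normalization and cyclic loess would both have raised the share left at day 6 above 0.6, but the higher of the 2 shares was 0.287, which argues against it. Had a compressed range on the day 6 arrays made the difference smaller, the slope across probes of day 6 on day 0 levels would have been at most 0.6. It was 1.002, which argues against a compressed range. A drift of each fraction back towards the mixture it was sorted from may be the biological side of this pattern, as a hypothesis. On the axis given above, Low and High lay nearer to Non-sorted at day 6. Non-sorted read 2862 for Car1 and 4017 for Hba-a1. Low went from 13637 to 5165 for Car1, towards that level, but from 7319 to 9695 for Hba-a1, away from it. High went towards it in both, from 64.9 to 1806 and from 34.2 to 2364. Over all tested probes the picture was mixed. The root mean square log2 distance to Non-sorted was 0.620 and 0.632 at day 0 and 0.617 at day 6 for Low. It was 0.743 and 0.622, then 0.829, for Mid, and 0.636 and 0.613, then 0.547, for High. The hypothesis stays open and untested. Day 6 has 1 array per fraction, and the handling of the cells between the days is not given in the sources used here.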

How the results depend on the processing

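The settings without both Mid arrays, without probes that had no day 0 spread and with day 0 fractions in place of Non-sorted cells were chosen after the results were seen. Of 2783 values of named genes over all alternatives, 2031 kept direction and side of the threshold, 732 lost the call, 6 gained it and 14 changed sign. The share of the Low minus High difference left at day 6 ran from 0.255 to 0.287 over all settings, and was 0.285 without either Mid array; without 1 Low or High array it could not be computed. Counts of probes are given in the order Low minus High, Low minus Mid and High minus Mid at day 0, Low minus High at day 6, the change between the days, day 6 minus day 0, and Epo minus Non-sorted. Leaving out each day 0 array in turn gave ranges of 12 to 2084, 23 to 4182, 0 to 3261, 0 to 1309, 0 to 1434, 0 to 4833 and 2568 to 4975. With all arrays the counts were 3553, 3962, 2559, 0, 16, 3076 and 4722. Over the same settings r ran from 0.380 to 0.397, and lists called ran from 7 to 8 (Low minus High at day 0), 5 to 8 (day 6) and 4 to 5 (Epo). Leaving out any array leaves 2 residual degrees of freedom, yet counts fell or stayed at 0 without a Low or High array and often rose without a Mid array, whose pair had the widest spread (SD of the pair difference 0.496, against 0.269 for Low and 0.348 for High); the cause was not tested. With no filter the counts were 173, 472, 337, 639, 682, 2902 and 2275, where all dim probes enter the test; the cause was not tested. Quantile normalization gave 1060 for High minus Mid, 5 lists for Low minus High at day 0 and r = 0.410; cyclic loess gave 1577, 5 lists and r = 0.410. The lower floor gave 5 probes for the change between the days and r = 0.356, the higher floor 1423 for High minus Mid, 28 for the change and r = 0.427. The generalised log gave 1 probe at day 6, 10 for the change and r = 0.425, and the stricter filter 1510 for High minus Mid, 1 at day 6, 28 for the change and r = 0.433. Without both Mid arrays 942 probes were called at day 6 and 1021 for the change. With an estimated correlation camera called 0 lists in each of the 3 list comparisons, where 8, 6 and 5 were called; fry called 0 at day 6 and 12 for Epo. With the replicate block, the counts were 1188, 2267 and 953 for the day 0 comparisons, 0 for the change, 0 for day 6 minus day 0 and 3009 for Epo. Arrays of the same letter did not deviate together (correlation of deviations 0.0777 for Low with Mid, −0.110 for Low with High and 0.0189 for Mid with High), so the letters are not taken to pair arrays. Among named genes and called lists, the signs that changed with quantile normalization were, for Low minus High at day 0, Mpo −1.04, Cox5b −0.0203, Ly6e −0.49 and the oxidative phosphorylation list (adjusted p = 0.894); for Low minus Mid, Gapdh 0.16; for High minus Mid, Mpo 0.00163, Gapdh 0.14, Tmem14c 0.26, oxidative phosphorylation (adjusted p = 0.974) and glycolysis (adjusted p = 0.960); at day 6, Mpo −0.30; and for day 6 minus day 0, Gapdh −0.0136. Among the same genes and lists, with cyclic loess they were Mpo −0.13 for Low minus High at day 0, Tmem14c 0.14 for High minus Mid and Mpo −0.0805 at day 6. Hba-a1 in High minus Mid, not called, stood at 0.57 without Mid replicate 1, −0.06 without High replicate 1 and −0.31 without Mid replicate 2. Directions of some lists that missed the threshold turned too. For all these moves the cause was not tested unless named. Signal over background limits the rest: 43.8% of probes could be tested, and a gene under the floor on 1 side has only a bound.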

Other observations

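Of the tests in this part, that of cells in the Epo state mixed into the Low fraction was chosen only after the result was seen, as were the counts at 4 cutoffs of rise that go with it.

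The 11 arrays can also be set by distance over all tested probes. Arrays of a day 0 pair differed by a root mean square of 0.269 (Low), 0.496 (Mid) and 0.348 (High) on the log2 scale, Low and High by 0.682 to 0.697 at day 0 and by 0.411 at day 6. The Epo culture was nearer to the day 0 Low arrays (0.860 and 0.875) than to the Mid (1.13 and 1.09) or High arrays (1.13 and 1.13), and 1.01 from Non-sorted cells. Red cell genes in Low did not stand at 1 level relative to the Epo culture: the Low minus High rise was 73.8% of the Epo minus Non-sorted rise for Car1, 13.0% for Hba-a1, 6.66% for Hbb-b2, 3.82% for Mgst3, a glutathione transferase gene chosen after its values were seen, and 0.926% for Ank1. Ank1 read 50.2 in Low and 5529 in the Epo culture. Dmtn averaged 4.64 in Low, under the floor, and 2410.1 in the Epo culture.

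A different scale of the bright range, as the cause of the resemblance between the Low fraction and the Epo culture, would have taken r below 0.1 within groups of like brightness, but the median over 6 groups was 0.427 after quantile normalization (range 0.101 to 0.481). A few erythroid genes with very large differences would have left at most 55% of the 906 shared calls with an absolute log2 difference below 1 with the same sign, but 77.2% had it; both values argue against these as the whole cause. Cells in the Epo state mixed into the Low fraction would give all 186 strongly raised probes a like ratio. The 90th percentile would then be at most 3 times the median. The value was 5.44, under the 10 times set as the bound against, so this test, written after its result was seen, does not decide. At the 4 cutoffs, 20.5% to 27.1% of probes had a ratio below 1% and 29.5% to 34.0% above 10%. A single share of cells at the levels of the Epo culture would not by itself give both. The Epo and Non-sorted levels in these ratios come from 1 array each. Cells at earlier or mixed stages could give uneven ratios, so a mixture of such cells cannot be told apart from a Low state of its own. That Low cells as a whole may lean towards the erythroid fate stays an untested hypothesis, because bulk arrays do not show how RNA is spread over cells.

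If the scale of the bright range made the rise of bright housekeeping lists in Low over High at day 0, each list's median would fall within the central 95% of 10000 random lists of matched brightness: the ribosomal protein median lay at percentile 32.0, oxidative phosphorylation at 31.5 and glycolysis at 66.8. Each median lay within that range, as the bright-range scale would give. A real rise of bright housekeeping RNA could give the same percentiles. The random lists were drawn from probes of like brightness, and many probes have no gene name here, so such RNA may be among them. The test therefore cannot tell the readings apart. The lists parted when quantile normalization took that scale out. The oxidative phosphorylation and glycolysis calls were lost (adjusted p = 0.894 and 0.943), while the ribosomal protein list kept its call (adjusted p = 0.00522) at a median of 0.24 in place of 1.09. Its call on the deposited values rests on the preset correlation (adjusted p = 0.431 with an estimated correlation). Whether the scale is the whole cause stays open for each of these lists. What sets that scale was not tested, and no biological explanation was tested.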
